A study of Mus musculus with 10 samples.

How the data were processed

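Total RNA of 10 tumours was sequenced on Illumina instruments, per the labels' protocols. It was extracted with TRIzol, per the labels' protocols, and whether the libraries kept the strand is not given in the sources used here. The authors deposited raw counts of reads per gene, 1 column per library. Reads were checked with FastQC, aligned with STAR and counted with featureCounts on mm10, per the submitters' processing notes, and the versions and settings are not given in the sources used here. No normalization had been applied to the deposited counts, which were whole numbers summing to 12013178 to 31530123 per library. Each column was matched to its library through the number in the sample's description. The replicate titles Arg and Control were read as the arginine-deficient and normal diets, from the design text of the series.

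The table held 21849 genes, of which 4263 were at 0 in every library. Gene symbols and positions came from GENCODE M21, which annotates the same build: 21379 identifiers matched with their version, 437 with another version, and 33 had no symbol. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 16.7, so all 10 counted as separate samples. The design text speaks of mice assigned to each diet at random by weight, so the libraries were taken as separate animals.

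Of the genes fixed in lists, 66 were at 0 in every library, B2m and Cxcl10 among them. As 57 of these 66 lay inside another gene's body, a 0 here was read as listed at 0, not as absent. The share of exonic bases inside other genes' bodies was computed for every gene and is given beside a named gene where it was 50% or more.

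The main test was edgeR 4.0.16 (R 4.3.3) quasi-likelihood F test with TMM factors and filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), with the diet as its only term. It kept 12929 genes holding 99.9% of counts. Standard errors were the log2 fold change over the square root of F, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values of tested genes were computed with the TMM factors, and those of muscle transcripts, haemoglobin and Gapdh per library from its total count without them. Before the data were examined, 39 gene lists were fixed; the 38 with at least 5 tested members were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The skin keratinocyte list had too few tested members. Single values were compared by exact two-sided permutation over the 252 assignments of libraries to diets, where the smallest possible p is 0.00794.

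Genes were named by a rule fixed before the data were examined. It took up to 12 genes in each direction with adjusted p under 0.05, mean CPM of at least 2 and no overlap between diets, excluding predicted models, pseudogenes and receptor segments. A direction with fewer than 4 was filled up to 6 by smallest p. It also took up to 4 members with the smallest p from each list described, and a panel of 26 genes. Of the genes it took, 1 is not reported here.

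The edgeR and camera steps were tested on 3 simulations of 200 changed genes each among the 12929 genes of the diet comparison. The test recovered 12.9% of genes changed 1.5-fold, 68.2% of those changed 2-fold and 99.0% of those changed 4-fold, with 18 false calls in all. Genes were simulated without correlation, so the simulations do not show how camera's preset behaves when genes move together. The changed genes were drawn from those averaging at least 2 CPM, and the MHC class I list was shifted beside them. Trends of single libraries with GC content and gene length were not simulated. With fewer changed genes or with such trends, recovery may be lower.

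Alternatives set out before the data were examined were other size factors, no filter or a stricter filter of at least 1 CPM in 5 libraries, DESeq2 1.42.0, limma voom with sample weights, a replicate block, each library left out in turn, a fold threshold of 0.5 on the log2 scale, off-tissue genes removed, thinning to the smallest total, camera with an estimated correlation, and fry. After the data were examined, 5 more were added: leaving aside the 3 libraries with most muscle transcripts, leaving aside the 2 with most Gapdh, removing genes with at least 50% of exonic bases inside other gene bodies, permuting list scores, and adding each library's slopes of log2 CPM on transcript GC content and gene body length as covariates. The last was added because a split of the libraries unrelated to diet called many genes.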

Results

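RNA was sequenced from 10 tumours grown under the skin of BALB/c mice from CT26 cells, a mouse colon carcinoma line. The mice were 5 weeks old at the start and ate either a normal diet or a diet of equal calories lacking arginine, for 1 week before the cells were implanted. Tumours were collected on day 20. There were 5 libraries from the arginine-deficient diet and 5 from the normal diet, each with one tumour's total RNA. Library totals ran from 12013178 to 31530123 counts, and 12929 genes had enough counts to be tested. Spread between tumours of one diet was wide, with a biological coefficient of variation of 26.5%.

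The libraries also differed in what tissue and RNA they held. Mitochondrially encoded genes took 9.97% of counts in arginine-deficient replicate 3, against 1.67% to 4.44% in the other libraries. Skeletal muscle transcripts summed to 9886 CPM (counts scaled to equal library totals) in that library, 2728 CPM in arginine-deficient replicate 4 and 997.7 CPM in normal-diet replicate 4, and to at most 235 CPM elsewhere. Haemoglobin transcripts averaged 91.4 ± 20.1 CPM (SD, n = 5) on the deficient diet and 313 ± 239 CPM (SD, n = 5) on the normal diet (exact two-sided permutation p = 0.0159, Benjamini-Hochberg adjusted p = 0.143 over 9 library measures). Those 9 hold muscle both as a percentage and as CPM, and no measure could have passed that adjustment on its own. Libraries differed further in how abundance depended on the GC content of a gene's transcripts, with slopes from -0.53 to 0.37 log2 units per 10 percentage points. That slope had nearly the same mean on both diets (exact two-sided permutation p = 1).

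**Figure D1:**
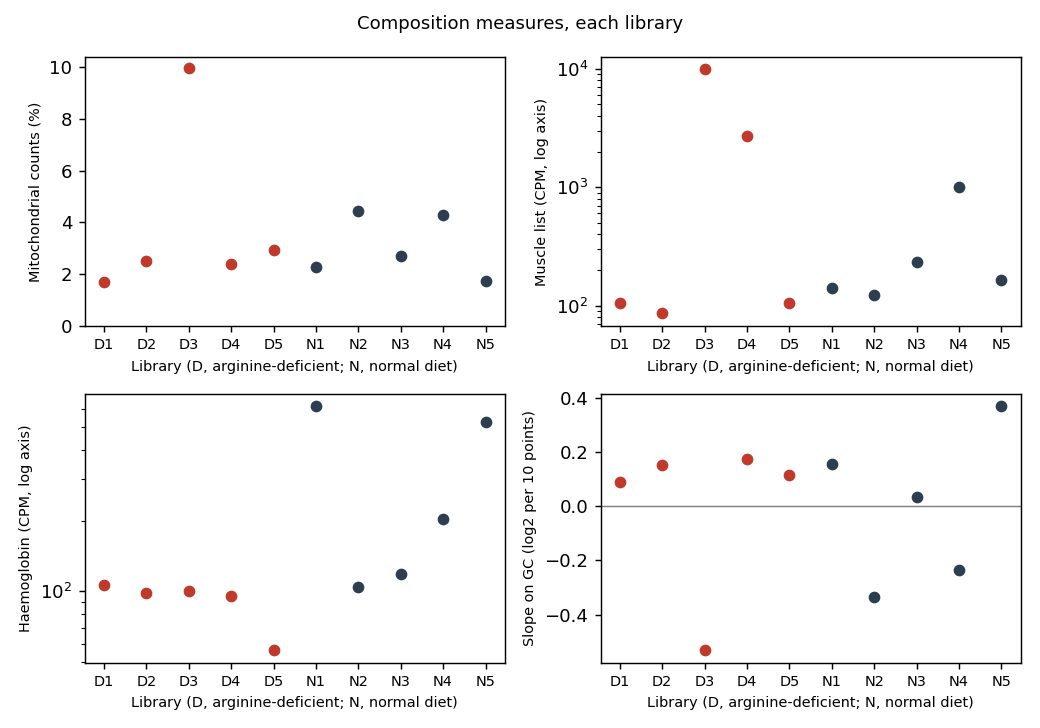
Mitochondrial counts (percent), skeletal muscle list (CPM, log axis), haemoglobin (CPM, log axis) and the slope of log2 abundance on transcript GC content in each of the 10 libraries, where D marks the arginine-deficient diet (red), N the normal diet (dark) and each point is 1 library. Arginine-deficient replicate 3 stands apart in mitochondrial counts (9.97%), muscle transcripts (9886 CPM) and GC slope (-0.53).

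The comparison of the diets asks which genes of the tumour respond to the loss of dietary arginine. 7 genes rose on the deficient diet and 0 fell (edgeR quasi-likelihood test, adjusted p under 0.05). Pycr1, which makes proline from pyrroline-5-carboxylate, rose from 9.19 ± 1.10 to 19.0 ± 1.75 CPM (SD, n = 5 each; log2 fold change 1.05, SE 0.14, adjusted p = 0.0158 by edgeR). Aldh1l2, a mitochondrial enzyme of folate metabolism, rose from 131 ± 24.1 to 341 ± 72.5 CPM (log2 fold change 1.38, SE 0.18, adjusted p = 0.0158 by edgeR). P2rx3, an ATP-gated ion channel known from sensory neurons, rose from 12.7 ± 3.62 to 62.3 ± 21.3 CPM (log2 fold change 2.29, SE 0.26, adjusted p = 0.00802 by edgeR). Car6, a secreted carbonic anhydrase, rose by 2.79 on the log2 scale (SE 0.41, adjusted p = 0.0354 by edgeR), and Mamdc2 by 2.86 (SE 0.32, adjusted p = 0.00802). Paqr3, a Golgi membrane protein, rose by 1.44 (SE 0.19, adjusted p = 0.0167 by edgeR). Akr1b7, an aldo-keto reductase, rose by 3.26 (SE 0.48, adjusted p = 0.0354 by edgeR), but it lies outside the naming rule because its mean stayed under 2 CPM, and 51.0% of its exonic bases lie inside the body of another gene. In each of the 7 genes every deficient-diet library was above every normal-diet library.

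**Figure D2:**
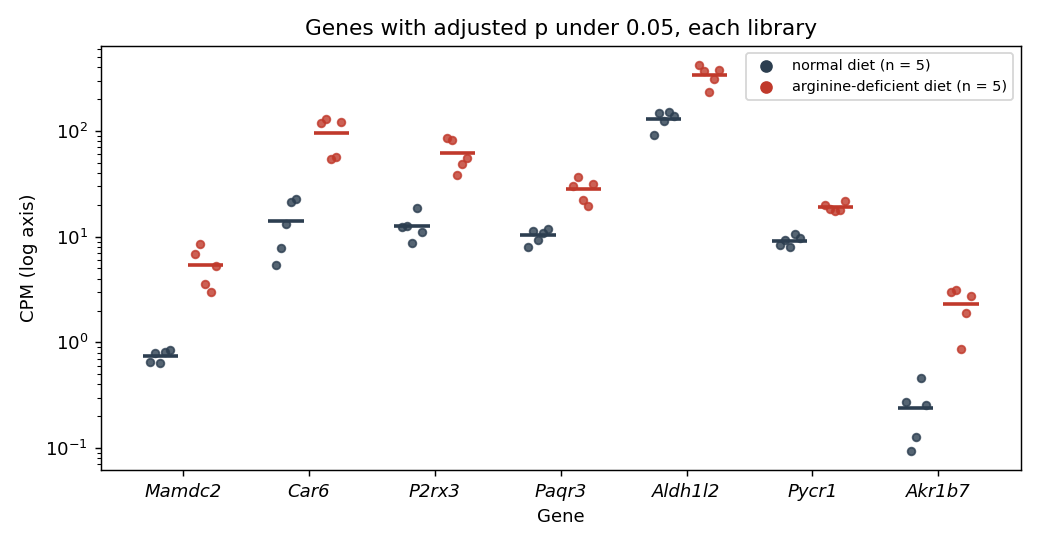
Abundance in CPM (log axis) of the 7 genes with adjusted p under 0.05, where each point is 1 library, horizontal lines are means, dark points are the normal diet and red points the arginine-deficient diet. The groups do not overlap in any of the 7 genes; Aldh1l2, the most abundant of them, averaged 131 CPM on the normal and 341 CPM on the deficient diet.

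On the mm10 build, Pycr1 (ENSMUSG00000025140.15) spans positions 120635712 to 120643769 of chromosome 11 and Aldh1l2 (ENSMUSG00000020256.14) spans 83487450 to 83534140 of chromosome 10. P2rx3 (ENSMUSG00000027071.14) lies at 84998583 to 85037462 of chromosome 2, Car6 (ENSMUSG00000028972.11) at 150187015 to 150201332 of chromosome 4 and Mamdc2 (ENSMUSG00000033207.7) at 23302609 to 23448442 of chromosome 19. Paqr3 (ENSMUSG00000055725.11) lies at 97082329 to 97111596 of chromosome 5 and Akr1b7 (ENSMUSG00000052131.7) at 34412334 to 34423142 of chromosome 6. These are gene bodies, exons and introns together, of protein-coding genes.

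Among genes lower on the deficient diet none passed, and the 6 named next are those of smallest p that averaged at least 2 CPM and met the naming rule. Tenm3, a teneurin of the cell surface, averaged 83.5 ± 8.15 CPM on the deficient and 126 ± 8.83 CPM on the normal diet (SD, n = 5 each; log2 fold change -0.60, SE 0.10, adjusted p = 0.0699 by edgeR). Gsg1, Cep112 and Msh5 had log2 fold changes of -0.87, -0.70 and -0.76, each with the same adjusted p of 0.0699 by edgeR, and 74.1% of the exonic bases of Gsg1 lie inside another gene's body. Ptpdc1 and Slco1a5 had log2 fold changes of -0.53 and -1.13 (adjusted p = 0.121 and 0.128 by edgeR). Outside the rule, picked after their values were seen, Vmn1r44 and Vmn2r78 averaged under 2 CPM and had log2 fold changes of -1.62 and -1.65, with the same adjusted p of 0.0699 by edgeR. At an unadjusted p under 0.05 there were 871 genes, 458 higher and 413 lower, where 646 are due by chance. In 213 genes (1.65% of those tested) the libraries of the diets did not overlap, against 0.794% by chance. No gene passed without normal-diet replicate 1 or without normal-diet replicate 3, and 2 passed without arginine-deficient replicate 1, 2 or 5 or normal-diet replicate 2, whereas 16 passed without arginine-deficient replicate 3 and 15 without normal-diet replicate 5. By choices made after the data were examined, 18 passed without the 3 libraries richest in muscle and 0 without the 2 with most Gapdh (907 at an unadjusted p under 0.05). With a replicate block 1 gene passed, P2rx3, and with a fold threshold of 0.5 on the log2 scale 2 passed. DESeq2 called 127 genes (68 higher, 59 lower), limma voom with sample weights 373 (205 higher, 168 lower), and edgeR with each library's GC and gene length slopes as covariates, a model chosen after the data were examined, 69 (35 higher, 34 lower).

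Genes of the amino acid stress response, targets of the transcription factor ATF4, lay higher on the deficient diet. All 34 tested members had a positive log2 fold change, with a median of 0.37; 1 of them, Pycr1, passed over all genes, and 3 passed adjusted over the list alone. Asparagine synthetase Asns averaged 528 ± 106 against 357 ± 23.1 CPM (SD, n = 5 each; log2 fold change 0.57, SE 0.14) and the cationic amino acid transporter Slc7a1 401 ± 81.9 against 279 ± 15.7 CPM (log2 fold change 0.52, SE 0.14). Nars, an asparaginyl-tRNA synthetase, had a log2 fold change of 0.42 (SE 0.13). The adjusted p of Asns, Slc7a1 and Nars over all genes was 0.283, 0.337 and 0.475 by edgeR. The list had an adjusted p of 5.92e-15 by camera with a preset correlation and an adjusted p of 0.430 with an estimated correlation. Its mean z-score per library was highest in deficient replicates 2 and 5 (1.19 and 1.04) and lowest among deficient libraries in replicate 3 (-0.74), which was also the library with the most mitochondrial and muscle counts.

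Genes of cholesterol synthesis lay lower. All 23 tested members had a negative log2 fold change, with a median of -0.30, and none passed on its own over all genes or adjusted over the list alone; 6 had an unadjusted p under 0.05. Nsdhl (log2 fold change -0.54, SE 0.16), Pmvk (-0.70, SE 0.22), Acat2 (-0.63, SE 0.20) and Fdft1 (-0.41, SE 0.15), enzymes of the pathway or of acetyl-CoA handling, had adjusted p of 0.457, 0.465, 0.466 and 0.589 by edgeR. The list had an adjusted p of 8.50e-09 by camera with a preset correlation and an adjusted p of 0.430 with an estimated correlation.

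Markers of M2-type macrophages lay higher in 18 of 22 tested members, with a median log2 fold change of 0.30; 0 passed over all genes and 5 passed adjusted over the list alone. The lectin gene Mgl2 averaged 21.4 ± 4.83 against 10.2 ± 4.77 CPM (SD, n = 5 each; log2 fold change 1.07, SE 0.30, adjusted p = 0.369 by edgeR) and the chemokine gene Ccl8 101 ± 12.7 against 58.3 ± 20.1 CPM (log2 fold change 0.79, SE 0.25, adjusted p = 0.465 by edgeR). Pdcd1lg2, the ligand PD-L2, had a log2 fold change of 1.49 (SE 0.41) at a mean of only 1.43 CPM over the libraries. F13a1 had 0.70 (SE 0.20), with 66.9% of its exonic bases inside another gene's body. The list had an adjusted p of 8.53e-06 by camera with a preset correlation and an adjusted p of 0.410 with an estimated correlation. General macrophage markers were split evenly, 14 higher and 14 lower, with a median of -0.01 and a mean of 0.02 (camera adjusted p = 0.696). Adgre1, which encodes F4/80, had a log2 fold change of -0.03 (SE 0.19) and Cd68 of 0.10 (SE 0.12). In the same list Mrc1 had 0.49 (SE 0.19), Fcgr3 0.21 (SE 0.11) and Trem2 -0.50 (SE 0.31), and none passed.

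**Figure D3:**
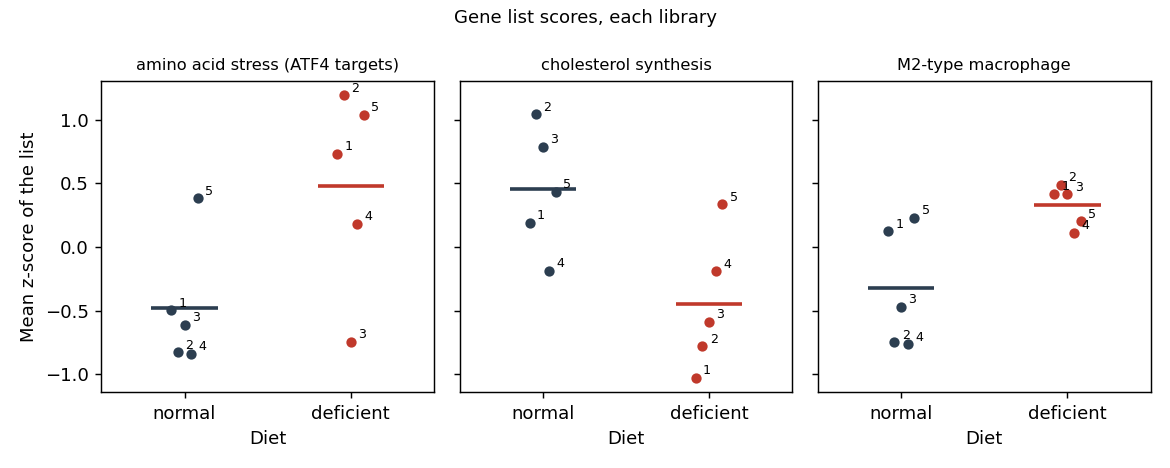
Mean z-score per library of 3 gene lists, where each point is 1 library with its replicate number, lines are means, dark points are the normal and red points the arginine-deficient diet. ATF4 targets lie higher in 4 of 5 deficient libraries than the normal-diet mean, with deficient replicate 3 at -0.74 and normal replicate 5 at 0.38.

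Among the genes of antigen presentation no member passed over all genes. In the MHC class II list 10 of 12 tested members were higher, with a median log2 fold change of 0.28 and no member passing (adjusted p = 0.00788 by camera with a preset correlation, adjusted p = 0.691 with an estimated correlation). Cd74, the invariant chain, averaged 745 ± 174 against 552 ± 200 CPM (SD, n = 5 each; log2 fold change 0.43, SE 0.26), and H2-Ab1 had a log2 fold change of 0.33 (SE 0.21), H2-DMb1 of 0.46 (SE 0.25) and H2-DMa of 0.23 (SE 0.12). Relative to the normal-diet mean, the median level of the list was -0.56 in normal-diet replicate 5 and 0.57 in normal-diet replicate 2, above every deficient library (-0.04 to 0.51), and the list was not called without arginine-deficient replicate 2 or normal-diet replicate 4 or 5. The cross-presentation list, genes by which cells place outside antigens on MHC class I, had 17 of 27 tested members higher and a median of 0.09 (adjusted p = 0.0389 by camera with a preset correlation, adjusted p = 0.430 with an estimated correlation). Arginine-deficient replicate 3, the library richest in muscle, had a median level of 0.38 over the normal-diet mean. By that measure the other deficient libraries (-0.06 to 0.07) lay within the range of the normal diet (-0.08 to 0.10). By mean z-score, deficient replicates 1, 2 and 3 (0.20, 0.16 and 0.60) lay above every normal-diet library (-0.47 to 0.10). Deficient replicates 4 and 5 (0.06 and -0.17) did not. The list was not called without arginine-deficient replicate 2 or 3 or normal-diet replicate 3 or 4. The translocon gene Sec61a1 (log2 fold change 0.46, SE 0.12), Derl1 (0.34, SE 0.11), Mrc1 (0.49, SE 0.19) and Atp6v0d2 (0.77, SE 0.32) had the smallest p in it, and none passed over all genes. Atp6v0d2 averaged only 1.65 CPM. MHC class I genes were split 10 higher and 10 lower, with a median of 0.01, a mean of -0.02 and a negative camera direction (adjusted p = 0.885). H2-K1 had a log2 fold change of -0.17 (SE 0.22), Tap1 of -0.00 (SE 0.17), H2-T22 of -0.29 (SE 0.15), Psmb9 of -0.34 (SE 0.20), Canx of 0.19 (SE 0.14) and Calr of 0.16 (SE 0.12). Of the type 2 and migratory dendritic cell markers 12 of 18 were higher, with a median of 0.05 (adjusted p = 0.0228 by camera with a preset correlation, adjusted p = 0.410 with an estimated correlation). Mgl2, Socs2 (log2 fold change 0.60, SE 0.16), Clec10a (0.76, SE 0.24) and Cd209a (0.92, SE 0.42, at a mean of only 0.968 CPM) led that list. Of its members 5, Mgl2 and Clec10a among them, are also in the M2-type list, and the other 13 had a median of 0.0083. The type 1 dendritic cell genes Xcr1, Clec9a and Batf3 had log2 fold changes of 0.34 (SE 0.55), 0.05 (SE 0.36) and -0.08 (SE 0.26).

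Genes of CD8 T cells, with CD200 the cells named in the title of the series, did not differ by more than the spread between tumours. Cd200 averaged 7.10 ± 3.29 CPM on the deficient and 6.49 ± 1.22 CPM on the normal diet (SD, n = 5 each; log2 fold change 0.13, SE 0.27, adjusted p = 0.998 by edgeR). Its receptor gene Cd200r1 had a log2 fold change of 0.21 (SE 0.23), Cd8a of -0.13 (SE 0.44) and Cd8b1 of -0.23 (SE 0.53). The killing genes Gzmb and Prf1 had log2 fold changes of 0.16 (SE 0.36) and 0.20 (SE 0.41). Ifng had 2 to 24 counts per library and was not tested. The T cell list was higher in 15 of 23 members (median 0.10, camera adjusted p = 0.0865; called with the replicate block and in 5 of the 10 fits that left out a library), led by Cd2 (log2 fold change 0.44, SE 0.28), Cd28 (0.70, SE 0.48), Zap70 (0.32, SE 0.24) and Cd4 (0.38, SE 0.31). The cytotoxic list was higher in 17 of 25 (median 0.10, camera adjusted p = 0.255), with Gzmk at -0.45 (SE 0.23), Nkg7 at 0.34 (SE 0.24), Ccl5 at 0.35 (SE 0.26) and Gzma at 0.51 (SE 0.39). The checkpoint list was higher in 14 of 24 (median 0.10, camera adjusted p = 0.162), with Pdcd1lg2, Ctla4 (0.71, SE 0.28), Cd274 (0.53, SE 0.26) and Cd244a (-0.58, SE 0.29) in front. The chemokine gene Cxcl9 had a log2 fold change of 0.34 (SE 0.30). B2m and Cxcl10 were listed at 0 in all 10 libraries.

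Genes that handle arginine were not called as a list: 17 of 29 tested members were higher, with a median log2 fold change of 0.12 (camera adjusted p = 0.111). The list was called higher without arginine-deficient replicate 1 or 4, and without the 2 libraries with most Gapdh, a choice made after the data were examined. Arg1, which breaks arginine down, averaged 143 ± 83.8 against 71.2 ± 29.3 CPM (SD, n = 5 each; log2 fold change 1.0, SE 0.37, adjusted p = 0.604 by edgeR). Nos2 had a log2 fold change of 0.54 (SE 0.30), Slc7a2 of 1.04 (SE 0.33), Nos1 of 1.56 (SE 0.65), Ass1 of 0.61 (SE 0.30) and Asl of -0.38 (SE 0.22). Nos1 and Ass1 averaged only 0.667 and 1.93 CPM. Arginine-deficient replicate 2 carried much of the difference in Arg1 (288 CPM) and Nos2 (39.9 CPM), whose log2 fold changes without it were 0.57 and 0.13, and arginine-deficient replicate 3 that in Nos1 (2.40 CPM), at 0.91 without it. Of the 23 tested genes of the panel fixed beforehand, 0 passed over all genes by edgeR, 4 had an unadjusted p under 0.05 and 2 passed adjusted over the list alone. Atf4 itself had a log2 fold change of 0.44 (SE 0.20), and Ddit3, a stress gene downstream of it, of 0.03 (SE 0.42).

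Among the remaining lists, genes of hypoxia and glycolysis lay higher in 31 of 37 members, with a median log2 fold change of 0.26 (adjusted p = 8.24e-05 by camera with a preset correlation, adjusted p = 0.691 with an estimated correlation). Relative to the normal-diet mean, its median level was -0.33 in arginine-deficient replicate 3, below every normal-diet library (-0.23 to 0.23). The other deficient libraries ran from 0.10 to 0.53. Ero1l, an oxidoreductase of the endoplasmic reticulum, averaged 616 ± 145 against 375 ± 90.2 CPM (SD, n = 5 each; log2 fold change 0.72, SE 0.20), P4ha2 had 0.67 (SE 0.23), Vegfa 0.56 (SE 0.23) and Pgam1 0.29 (SE 0.10). Proliferation genes lay lower in 32 of 39 members, with a median of -0.10 (adjusted p = 0.00239 by camera with a preset correlation, adjusted p = 0.588 with an estimated correlation). Cyclin B2, Ccnb2, averaged 62.5 ± 5.97 against 88.5 ± 6.61 CPM (SD, n = 5 each; log2 fold change -0.50, SE 0.10, adjusted p = 0.163 by edgeR) and was the 1 member that passed adjusted over the list alone; Kif2c, Cenpa and Aurkb had -0.32, -0.24 and -0.23. Endothelial markers lay lower in 17 of 22 members, with a median of -0.13 (adjusted p = 0.00834 by camera with a preset correlation, adjusted p = 0.430 with an estimated correlation), among them Robo4 (-0.28, SE 0.12), Cldn5 (-0.69, SE 0.32), Esam (-0.22, SE 0.11) and Erg (-0.32, SE 0.19). Immediate early and heat shock genes lay higher in 21 of 24, with a median of 0.19 (adjusted p = 0.00802 by camera with a preset correlation, adjusted p = 0.772 with an estimated correlation), with the smallest p in Hspa8 (0.57, SE 0.18), Zfp36 (0.39, SE 0.16), Hspb1 (1.38, SE 0.63) and Klf6 (0.29, SE 0.14). The median level of that list ran from -0.18 to 0.52 on the deficient and from -0.54 to 0.43 on the normal diet. Its call was lost in 4 of the 10 fits that left out a library. Hspb1 was high only in the muscle-rich arginine-deficient replicates 3 and 4 (7.50 and 12.3 CPM), against a mean of 1.87 CPM on the normal diet. Skeletal muscle genes had a median of 3.36, all 16 higher (adjusted p = 0.0254 by camera with a preset correlation, adjusted p = 0.837 with an estimated correlation), with Tnni2 at 2.84 (SE 1.18), Neb at 3.35 (SE 1.42), Pygm at 3.28 (SE 1.40) and Des at 2.76 (SE 1.20). Without arginine-deficient replicate 3 alone, the mean of that list was 1.35 (camera adjusted p = 0.951), and these 4 genes had 1.13, 1.08, 1.33 and 1.87. Without the 3 libraries richest in muscle, a choice made after the data were examined, the mean of that list turned to -1.33 (camera adjusted p = 0.00723). Of the erythroid and platelet genes 5 of 7 were lower, with a median of -1.65 (adjusted p = 0.0420 by camera with a preset correlation, adjusted p = 0.691 with an estimated correlation). The haemoglobin genes Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2 had log2 fold changes of -1.72, -1.86, -1.65 and -1.66 and passed adjusted over the list alone, and near-identical copies among them can share reads. Normal-diet replicates 1 and 5 carried this (haemoglobin 613 and 524 CPM), while normal-diet replicates 2 and 3 (104 and 119 CPM) lay near the deficient libraries (56.1 to 106 CPM), and the list was called in 8 of 22 other settings of camera with a preset correlation.

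**Figure D4:**
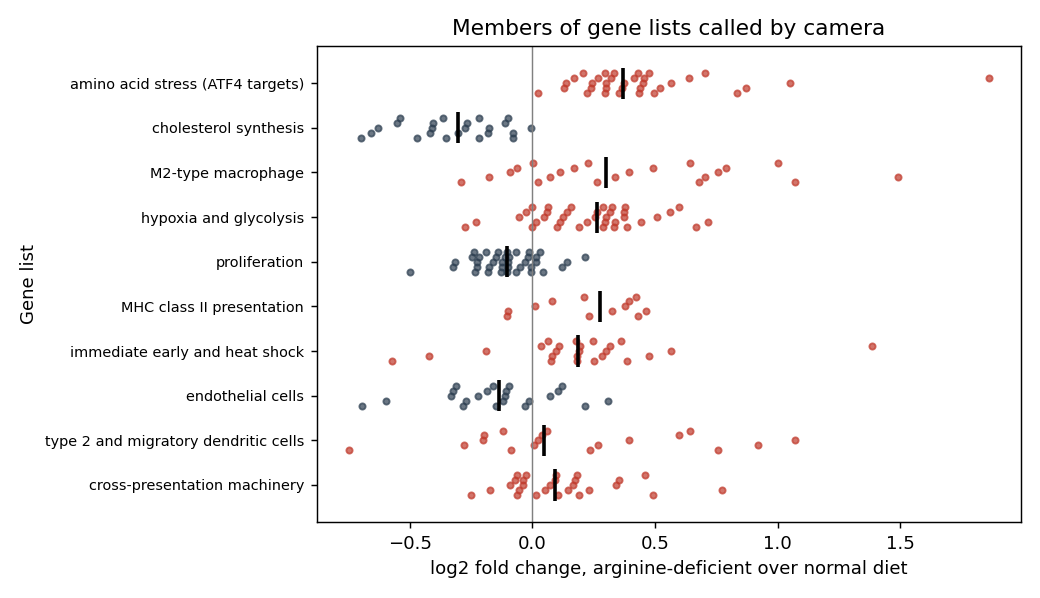
Log2 fold change of each tested member (points) of 10 of the 12 gene lists called by camera with a preset correlation, with the median as a black bar; red lists were called higher and dark lists lower on the arginine-deficient diet. All 34 ATF4 targets lie above 0 and all 23 cholesterol synthesis genes below 0.

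Over the 38 lists tested, camera with a preset correlation called 12, of which 8 higher and 4 lower. None was called with an estimated correlation (lowest adjusted p = 0.410; 3 lists at an unadjusted p under 0.05), with fry (5 lists at an unadjusted p under 0.05), or by an exact permutation of the list scores (4 lists at an unadjusted p under 0.05). When the 10 libraries were split into 5 and 5 at random, 60 of 100 splits, the real one included, called 12 or more lists by the same test. Leaving out arginine-deficient replicate 2 left 5 called lists, and leaving out arginine-deficient replicate 4 gave 19.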

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

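Except for the counts of random splits and the length and GC correction of the ATF4 list, the tests in this part were chosen after the results they bear on were seen, the GC and length trend of the mixed split among them. In 290 groups of 5 values, 31 held a library whose gap to its nearest neighbour was over 0.71 of the group's range. For normally distributed values chance gives about 1 in 20 groups, or 14.5. CPM and percentages were used untransformed and need not be normal, and values of one library are not independent.

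Arginine-deficient replicate 3 was set apart most often. It had 9.97% mitochondrial counts (the other deficient libraries 1.67% to 2.92%), 10.3% of counts in its top 10 genes (5.02% to 6.02%), 9886 CPM of muscle transcripts, and a GC slope of -0.53 log2 units per 10 points (0.09 to 0.18). In muscle genes it had 290 CPM of Tnni2, 649 CPM of Neb and 184.0 CPM of Pygm. It was also high in Cd200 at 12.8 CPM (4.91 to 6.78), Cd200r1 at 17.8 CPM (7.86 to 10.2), Xcr1 at 7.93 CPM (1.98 to 3.68) and Nos1 at 2.40 CPM (0.359 to 0.950). Normal-diet replicate 4 held 997.7 CPM of muscle transcripts, with 28.6 CPM of Tnni2, 50.9 CPM of Neb and 16.3 CPM of Pygm, and had the lowest Ccl8 of its group at 22.99 CPM (63.1 to 72.3).

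Normal-diet replicate 5 had 2.22% ribosomal protein counts (the other normal-diet libraries 1.02% to 1.27%), a ribosomal protein list score of 1.88, 137 CPM of Gapdh (51.1 to 60.1), 475 CPM of Nars (403 to 413), 11.4 CPM of Cldn5 (3.56 to 5.49) and 1.85 CPM of Ctla4 (3.51 to 4.17). Its ATF4 target score of 0.38 was the highest of the normal diet (-0.84 to -0.50). Arginine-deficient replicate 2 had 288 CPM of Arg1 (86.7 to 137), 39.9 CPM of Nos2 (12.8 to 19.0), 50.1 CPM of Gzma (16.2 to 18.5) and 13.5 CPM of Cep112 (15.4 to 16.1). Arginine-deficient replicate 5 had 56.1 CPM of haemoglobin (95.4 to 106) and 73.8 CPM of Fdft1 (49.7 to 52.7). Normal-diet replicate 2 had 191 CPM of Cxcl9 (85.5 to 109) and 29.1 CPM of H2-DMb1 (15.1 to 17.3).

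Of 100 splits of the 10 libraries into 5 and 5, 2 called at least 7 genes, the real one included, so as many genes were seldom called by chance. The other one called 1260 genes, which points to a structure of the libraries that is not the diet. That split sets arginine-deficient replicates 1 and 3 and normal-diet replicates 2, 3 and 4 against the rest. A trend with gene length and GC content may account for it: length, GC content and abundance account for 48.1% of the variance of its log2 fold changes and 0.658% of that of the diets, and its 525 higher genes have a median GC content of 43.9% and body length of 79.996 kb against 57.0% and 9.45 kb in its 735 lower genes. With each library's GC and length slopes as covariates, a model chosen after the data were examined, that split called 0 genes. The sides did not overlap in GC slope (-0.53 to 0.09 against 0.11 to 0.37), so these covariates can take up other differences between them. That 0 therefore goes with the trend but cannot decide. Skeletal muscle in some of the tumours was weighed by leaving out the 3 libraries richest in muscle. Of the called genes 99.9% then kept at least 0.5 of their log2 fold change (median share kept 0.873), and no gene was called. These values cannot decide, since the genes were called in these same libraries. In each of 49 other ways to leave out as many libraries from each side, at least 96.1% kept as much. The median share was lower in 9 of the 49, and no gene was called in 31. Over all tested genes without the muscle-rich libraries, length, GC content and abundance still accounted for 37.1% of the variance. This argues against muscle as the whole cause of that trend. What made the libraries differ in GC content, in the tissue or in the laboratory, stays open and was not tested.

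With the GC and length slopes of each library as covariates, the real split called 69 genes, and 1 of 100 splits, the real one, called as many; the highest of the others called 59 and the next highest 2. That model was chosen after the data were examined, and only the count of its splits was predicted in advance. Lists behaved otherwise: 60 of 100 splits called at least 12 lists (highest other 25), and with the covariates 83 of 100 called at least 8 (highest other 23), so chance cannot be excluded as the source of the number of lists called by camera with a preset correlation.

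The ATF4 target list, all 34 members higher with a median of 0.37, was weighed against 3 technical or chance explanations. Off-tissue and mitochondrial RNA shifting the normalization was weighed by taking out the genes of those lists, which left 12857 genes tested. The median was then 0.372, which argues against those listed genes as the source. Other transcripts of the same tissues stayed in, so a shift by off-tissue RNA as a whole was not decided. Gene length and GC content as the whole cause is argued against too, since the median residual after correction for both and for abundance was 0.321. Differences between single tumours stay open, as the exact permutation of the list score gave p = 0.0714 (adjusted p = 0.452 over the lists), with scores of -0.74 in arginine-deficient replicate 3 and 0.38 in normal-diet replicate 5, the libraries at the ends of the GC slope. The removal of arginine from the diet stays open beside it as the biological explanation.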

How the results depend on the processing

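Settings named here as added were chosen after the data were examined. The 7 higher genes were all called with other size factors (7 genes in each), without a filter (8 genes), by DESeq2 (127: 68 higher, 59 lower) and by voom with sample weights (373: 205 higher, 168 lower). A stricter filter and the added removal of genes inside other gene bodies called 6, both losing Akr1b7. Thinning called 7, of which 6 were among the original genes, and removing off-tissue genes called the same 7. The fold threshold called 2, both higher. The added covariates for GC and length slopes called 69 (35 higher, 34 lower), all 7 among them. Leaving aside the 3 libraries with most muscle transcripts (added) called 18, all higher and the 7 among them, and leaving aside the 2 with most Gapdh (added) called 0 by edgeR, with 907 genes at an unadjusted p under 0.05. Leaving out single libraries gave 0 to 16 genes, 0 to 15 higher and 0 to 4 lower. The count was 0 without normal-diet replicate 1 or 3, 16 without arginine-deficient replicate 3 and 15 without normal-diet replicate 5. Apart from settings with fewer samples or genes, the cause was not tested.

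The replicate numbers of the titles are shared by both diets. The deviations of same-numbered libraries correlated from -0.349 to 0.183, with 3 of 5 over 0.1 and 1 of 5 deficient libraries correlating best with its own number. No pairing by number was seen, though correlations over all tested genes cannot exclude one. With the replicate block the count was 1, that 1 higher, P2rx3, and 12 lists were called. Values under the block changed sign for Cd8a (0.10), Cd8b1 (0.029), Ddit3 (-0.016) and Adgre1 (0.019), none of them passing.

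No list was called with an estimated correlation, with fry or by permuting list scores (added), the last of which could not have called a list on its own. Other settings called 8 to 13 lists, with 7 to 12 of the original 12 among them. Leaving out single libraries gave 5 to 19 lists, with 5 to 11 of the 12 among them, the fewest without arginine-deficient replicate 2 and the most without arginine-deficient replicate 4. In 22 settings by camera with a preset correlation, the ATF4, cholesterol, M2-type and hypoxia lists were always called, and proliferation and endothelial genes were lost in 1. MHC class II and type 2 dendritic cells were lost in 5 each, immediate early genes in 4, muscle in 8, cross-presentation in 10 and erythroid genes in 14, counting the setting that removes muscle and erythroid genes.

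The remaining sign changes were in results that did not pass, except the muscle list; lists are given as mean log2 fold changes. Without the 3 libraries richest in muscle the muscle list was -1.33 (camera adjusted p = 0.00723), macrophages -0.049, T cells -0.10, Tnni2 -0.69, Neb -0.66, Pygm -0.69, Des -0.81, Hspb1 -0.37, Cd200 -0.11, Cd200r1 -0.027, Xcr1 -0.24, Clec9a -0.12 and Tap1 0.046. With voom the muscle list was -0.26, T cells -0.12, MHC class I 0.11, Cd200 -0.026, Clec9a -0.24 and Tap1 0.12. Without the 2 libraries with most Gapdh, T cells were at -0.012, MHC class I at 0.083, Tap1 at 0.076, Clec9a at -0.16 and Batf3 at 0.077. Tap1 was 1.44e-04 without a filter and Clec9a -0.024 after thinning.

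Leaving out single libraries moved macrophages from -0.049 to 0.062, MHC class I from -0.12 to 0.060, T cells from -0.072 to 0.26, cytotoxic genes from -0.12 to 0.27 and checkpoint genes from -0.0022 to 0.25. T cells were called higher by camera without arginine-deficient replicate 4 (adjusted p = 0.0306) or 5 (0.0182), without normal-diet replicate 1 (0.00888), 2 (0.00338) or 3 (0.0122), and with the replicate block (0.0149). Checkpoint genes were called without arginine-deficient replicate 4 (0.0351) or normal-diet replicate 2 (0.0379), and cytotoxic genes without normal-diet replicate 1 (0.0236). Arginine and polyamine genes were called without arginine-deficient replicate 1 (0.0488) or 4 (0.0351) and without the 2 libraries with most Gapdh (0.0186). The ranges of log2 fold changes were -0.19 to 0.23 for Cd200, -0.065 to 0.30 for Cd200r1, -0.39 to 0.23 for Cd8a, -0.52 to 0.085 for Cd8b1, -0.23 to 0.39 for Gzmb and -0.22 to 0.49 for Prf1. They were -0.19 to 0.39 for Ddit3, -0.15 to 0.091 for Tap1, -0.079 to 0.82 for Xcr1, -0.12 to 0.35 for Clec9a, -0.20 to 0.054 for Batf3 and -0.14 to 0.17 for Adgre1. At this depth and spread 12.9% of simulated 1.5-fold changes were recovered, so changes of that size were mostly not detectable.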

Other observations

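The tests in this part were chosen after the results they bear on were seen. With the GC and length slopes as covariates, a model also chosen after the data were examined, edgeR called genes that the comparison without them did not. Avil, an actin-binding protein known from sensory neurons, rose by 2.40 on the log2 scale (SE 0.23, adjusted p = 0.00829). Klf15, a transcription factor, rose by 2.01 (SE 0.33, adjusted p = 0.0324) at a low abundance, with an average log2 CPM of only 0.63. Xbp1, a factor of the unfolded protein response, rose by 0.46 (SE 0.08, adjusted p = 0.0360), and Selenos and Wfs1, both of the endoplasmic reticulum, by 0.48 and 0.73 (SE 0.09 and 0.13, adjusted p = 0.0481 and 0.0476). The glycogen genes Gys1 and Pygl rose by 0.55 and 0.63 (adjusted p = 0.0392 and 0.0481). Tenm3 (-0.58, SE 0.06, adjusted p = 0.00829), Ccnb2 (-0.50, SE 0.09, adjusted p = 0.0421), Brca2 (-0.44, SE 0.08, adjusted p = 0.0397) and the matrix gene Thbs2 (-0.66, SE 0.10, adjusted p = 0.0257) fell. These genes were picked from the 69 after their values were seen.

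Lists of other cell types and programmes were not called by camera in the main comparison, though some were when a library was left out. Fibroblast and matrix genes were split 16 higher and 16 lower (median log2 fold change 0.00, adjusted p = 0.940), and type 1 dendritic cell markers 10 higher and 5 lower (median 0.09, adjusted p = 0.899). Type I interferon genes had a median of 0.04 (adjusted p = 0.224), interferon-gamma genes 0.07 (adjusted p = 0.327), oxidative phosphorylation -0.05 (adjusted p = 0.333) and natural killer cell markers 0.15 (adjusted p = 0.255). In several lists the signs differed: neutrophil markers had a median of -0.03 and a mean of 0.05 (adjusted p = 0.440), and regulatory T cell markers a median of -0.03 and a mean of 0.07 (adjusted p = 0.611).

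Genes at 0 in every library were weighed as a counting effect, and no biological explanation was tested for them beyond lack of expression. Of 947 list genes with coordinates 66 were at 0, and 86.4% of these lay with at least 99% of their exonic bases inside another gene's body, against 0.341% of the 881 that were counted (Fisher's exact test p = 6.2e-78). Lack of expression is argued against for genes inside another gene's body, of which 95% were at 0, all 39 enclosed only by genes of the other strand among them, against 1.01% of the others, and a loss of reads only where exons overlap is argued against too, since 1.52% of the genes at 0 had their exons inside other genes' exons. Among all 21816 genes with coordinates 30.8% of the 4244 at 0 lay so, and 14.5% of the genes not enclosed were at 0, so most zeros of the table as a whole are not accounted for in this way. Counting over whole gene bodies without strand, with reads in more than 1 gene dropped, may therefore have removed genes such as B2m and Cxcl10 from the table.

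The M2-type markers may have moved apart from macrophages as a whole. Without shared members, the M2-type list minus the macrophage list was 0.41 log2 units higher per library on the deficient diet (exact permutation p = 0.00794, the smallest this design can give), which argues against a larger share of macrophages as the whole cause. The 5 markers shared with the type 2 dendritic cell list are argued against as the whole source, since the median was 0.226 without them against 0.302 with them. Whether the other 17 members also come from type 2 dendritic cells was not tested, so that cell type stays open. Both tests used a list that had already been seen to lie higher.

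Sensory nerve tissue was tested as a source of P2rx3, with 30 other sensory neuron markers written down before the test. Of these, 7 had enough counts to be tested, 2 of them higher and 5 lower, with a median log2 fold change of -0.23 (lowest unadjusted p = 0.153). These markers do not decide, since 3 of the 7 lay under 1 CPM and Runx1, the most abundant, is not specific to nerves. Avil goes with the explanation, at 2.48 (SE 0.46, adjusted p = 0.0956 by edgeR) without covariates as well. It was not among the 30 markers and was picked after its value was seen, so it does not decide either. Sensory nerve tissue stays open. Nefm was the most abundant nerve filament gene among them and had a log2 fold change of -0.29 (SE 0.30).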
